A study of Capra hircus with 6 samples.

How the data were processed

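Mammary gland RNA of 6 lactating goats, 3 of the Low and 3 of the High CSN1S1 genotype, was measured on 6 arrays with 2 dyes. Each array held 1 Low and 1 High goat, each of the 3 pairs of goats was hybridized on 2 arrays with Cy3 and Cy5 exchanged, and 5 µg of total RNA was labelled directly per sample, per the labels' protocols. The pairing comes from the labels, which give the goats hybridized together, and from their being on the same array. The image names in the file headers carry the same goat number and dye as the labels in 12 of 12 files, and the genotype codes FF for Low and AA for High goats.

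The deposited scanner files give, per dye channel, the signal and background intensity of each of 19200 spots on a linear scale with the background not subtracted. They were read with ImaGene 6.0 per the labels, version 6.0.1 per the file headers. Of the spots, 16758 carry 8379 probes spotted 2 times each, 906 are named blank and 1536 empty. The scanner software's flag codes 1, 2 and 3 were taken as manual, empty and poor spots, because their counts equal those per the file headers in 12 of 12 files. The deposited series table holds the authors' log2 ratio of Low over High for every spot. Its scale and direction were settled by setting it against the scanner files: within 20 intensity bins it followed the log2 ratio of the signal means with a correlation of at least 0.994 and slopes between 0.985 and 0.996. Its columns have medians from -0.014 to 0.0034, and how the authors normalized them is not given in the sources used here.

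The main values were computed from the signal mean and background mean with limma 3.58.1 in R 4.3.3. Background was corrected with normexp and an offset of 50, and each array was normalized with 1 loess curve in which blank, empty and left-out spots had no weight. Manual and poor spots, 26 to 67 per array, were left out, and empty flags (4430 to 5136 per array, many on control spots) were not. Saturated probe spots, 0 to 9 per reading, were kept. The spots of a probe were averaged, ratios were turned to Low over High, and the 2 arrays of a pair were averaged, which removes a dye effect that is equal on both. A probe was tested when its signal exceeded the background by 2 background SDs in at least 6 of the 12 channel readings and it had a value on all 6 arrays, which 6733 probes did. Duplicate spots on an array had an SD of 0.080 to 0.10 on the log2 scale. A linear fold for a named gene above background in fewer than 3 of the 6 Low readings was bounded from single channels after loess and Aquantile, with each Low reading raised at least to the lowest signal above background on its array.

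The test was limma's moderated test of the 3 pair means against 0, with Benjamini-Hochberg adjustment over the tested probes and a threshold of 0.05. P-values rest on the spread between the 3 pairs of goats, combined with a spread pooled over the tested probes. The pooled part has 7.47 degrees of freedom against 2 from a probe's own pairs, so it carries most of the weight. In a t-test on a probe's own spread alone 0 probes passed. Lists were tested with camera (preset correlation 0.01), with 1 probe per gene, the brightest, among 5323 genes. Of 31 lists, 29 had at least 4 measured genes and were adjusted together. The lists, the main test and the alternatives were fixed before the data were examined, apart from 4 alternatives named in the closing section.

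Genes were named by this rule: among probes past the threshold with the same sign on all 6 arrays, the 15 largest falls and rises. Where fewer than 10 passed in a direction, the probes of smallest unadjusted p with the same sign on all 6 arrays filled the list up to 10, and they are said not to pass. Up to 3 members of each list with the smallest p and the major milk protein genes were added, and where several probes qualified the brightest was named. POLR1D closes the 15 falls, and GPX2 is named as a member of its list. Gene symbols come from the platform annotation given for the series' probes, in which 6840 probes have 1 symbol, 93 several and 1446 none, and no gene is named from a probe with several except where said. Of 6535 symbols, 6020 are also symbols or synonyms in the goat gene table of assembly ARS1.2. Its coordinates were not used, since the sources name no genome build.

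The procedure was tested on simulated arrays built from the real intensities, the mean dye effect of each probe and the pooled spread. At a simulated 1.25-fold change 98.5% of the changed probes were recovered, and at 1.5-fold and 2-fold 100%, of 8061 probes tested. Of the probes left unchanged, 15 were called, which was 6.98% of all calls. The simulated signals passed the filter more often than the real ones, so these shares are optimistic for dim probes. Each probe's dye effect was the same in all simulated pairs, so it cancelled between the arrays of a pair. Real dye effects differed between pairs. The simulated spread was drawn from the test's own pooled model, and more probes were changed than were called in the real data. The shares therefore do not carry over to the real arrays. A simulated list of 20 genes shifted by -0.1 was called and 0 of the other 28 lists were. The simulated probes varied independently of one another, and the shift was larger than the ribosomal list's median of -0.043. The list result therefore does not carry over to genes that vary together or to smaller shifts.

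Alternatives changed 1 choice at a time, except that block medians came with no background correction that a trended prior came with a robust one, and that leaving out 1 array came with a limma fit on arrays with a dye term and the pair as a random block. In the t-test, the trended prior and the random-block fits, lists were tested on the t-statistics with cameraPR. They changed the background correction, its offset, the normalization, the filter on dim probes, the flags, the test, the model (arrays with a dye term, unpaired goats), the dye orientation, the deposited series values, the threshold, the list test, and leaving out each pair.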

Results

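RNA from the lactating mammary gland of 6 goats was compared on 6 arrays that hybridize 2 samples at a time, each in its own dye. The goats differed in genotype at CSN1S1, the gene of alpha-s1-casein, a major milk protein. In each of 3 pairs, A, B and C, a goat of the Low genotype was set against a goat of the High genotype, and all 6 goats had been without food for 48 h. Each pair was hybridized on 2 arrays with the dyes exchanged, so the 2 arrays of a pair measured the same RNA and were averaged, which left n = 3 pairs of different goats. Values are log2 ratios of Low over High, so a negative value means a lower signal in the Low goat. The arrays carried 8379 bovine oligonucleotide probes, each spotted 2 times, and 6733 probes passed the filter on dim signals. Median signal over background lay between 2.67 and 6.00 per dye reading. Between 66.3% and 77.3% of probes stood above background in Cy3 and between 82.3% and 87.4% in Cy5. The number of pairs, 3, limits the precision: the median standard error of a log2 ratio was 0.04.

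The series asks how the CSN1S1 genotype relates to expression in the gland of fasted goats, so the gene itself was read first. CSN1S1 fell by 2.71 ± 0.13 on the log2 scale (SD, n = 3), a 6.55-fold lower signal in Low goats (limma adjusted p = 2.91e-09). The 3 pairs gave -2.57, -2.84 and -2.73, and the 6 arrays lay between -3.10 and -2.52. Its probe stood above background in every reading of both genotypes. None of the other major milk protein genes passed the threshold. The log2 ratio of LALBA, which encodes the alpha-lactalbumin subunit of lactose synthase, was 0.55 ± 0.46 (SD, n = 3; adjusted p = 0.170) with 0.68, 0.94 and 0.04 in pairs A, B and C, and it was above 0 on 6 of 6 arrays. CSN1S2, the gene of alpha-s2-casein, gave 0.75 and 0.53 in pairs A and B and -0.29 in pair C. PAEP, the gene of beta-lactoglobulin, gave -0.71 and -0.66 in pairs A and C and 0.06 in pair B. For CSN3, the kappa-casein gene, the brighter probe gave -0.10 ± 0.21 (SD, n = 3) and its other probe -0.07. A probe annotated to both CSN3 and CSN2 gave -0.09, and no probe carried CSN2, the beta-casein gene, alone. LTF, the gene of the antimicrobial milk protein lactoferrin, was below 0 on 6 of 6 arrays but varied between pairs, at -1.31, -0.35 and -0.35 (adjusted p = 0.170).

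**Figure D1:**
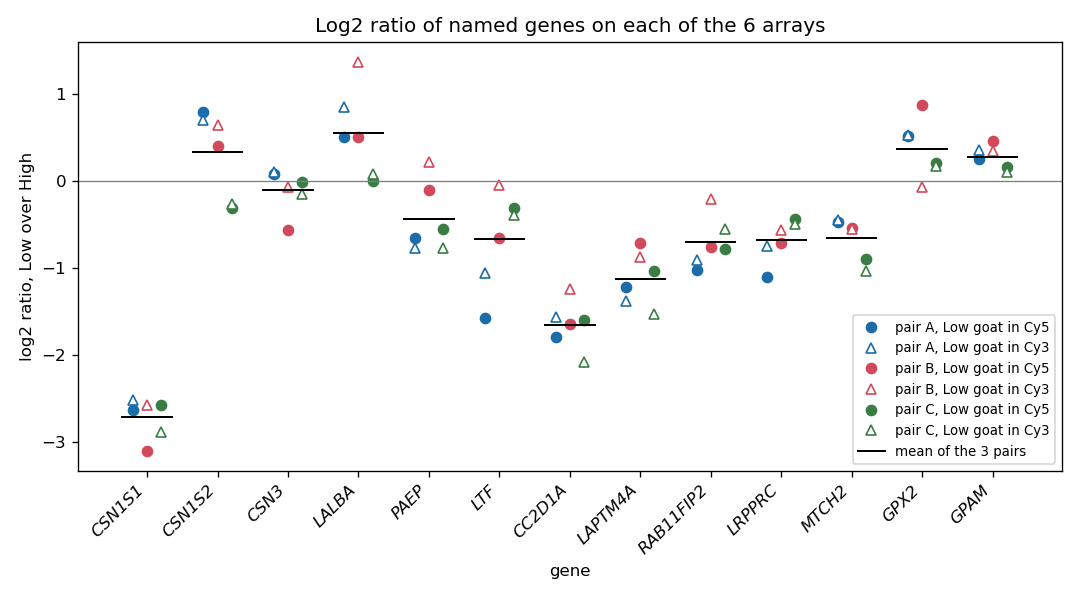
Log2 ratio of Low over High (vertical axis) for 13 genes (horizontal axis). Points are the 6 arrays, coloured by pair, filled circles with the Low goat in Cy5 and open triangles with it in Cy3, and the line is the mean of the 3 pairs. CSN1S1 lies between -3.10 and -2.52 on the 6 arrays, while LALBA, CSN1S2 and PAEP differ between pairs.

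Across the array, 30 probes changed between genotypes, 28 lower and 2 higher in Low goats, and 25 of the 30 had the same sign on all 6 arrays. After CSN1S1, CC2D1A, a transcriptional repressor and signalling scaffold, fell (fitted log2 ratio -1.65 ± 0.20, SD, n = 3; adjusted p = 1.40e-06). It stood above background in 1 of 6 Low readings and 6 of 6 High readings, so its signal was at least 3.00-fold lower in Low goats. LAPTM4A, a lysosomal membrane protein gene, fell by 1.12 ± 0.29 (2.17-fold lower, adjusted p = 4.48e-04). RAB11FIP2, an effector of Rab11 in endosome recycling, was at -0.70, LRPPRC, an RNA-binding protein of mitochondrial transcripts, at -0.67, MTCH2, a mitochondrial outer-membrane protein, at -0.66, and ADHFE1, a dehydrogenase family member, at -0.51. Smaller falls were those of FYN, a Src-family kinase (-0.39), MRPS6, a mitochondrial ribosomal protein (-0.38), LGI1 (-0.38), PHLDB3 (-0.37), HSD11B1, which regenerates active glucocorticoid (-0.34), and VAC14, a scaffold of endosomal lipid kinase (-0.31). These genes are listed by size of change, and no test grouped them. WASHC2A, a subunit of the endosomal WASH complex, was not well above background in any Low reading, so its signal was at least 1.45-fold lower in Low goats (adjusted p = 0.00127, fitted log2 ratio -0.55).

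The 2 probes past the threshold in the other direction were GTSE1 and GPX2. GTSE1, a cell-cycle protein gene, was 0.22 ± 0.04 higher (SD, n = 3; 1.17-fold, adjusted p = 0.0385) and above 0 on 6 of 6 arrays. GPX2, a glutathione peroxidase gene, was 0.37 ± 0.17 higher (1.29-fold, adjusted p = 0.0262) and above 0 on 5 of 6 arrays. Of 21 alternatives fixed in advance GTSE1 passed in 8 and GPX2 in 11. The count of higher probes was 0 with print-tip loess, offset 10, the series values, no background correction and no flagged spot left out. Leaving out a pair gave 22 higher probes without A, 0 without B and 5 without C. GPAM, the acyltransferase that starts glycerolipid synthesis, was at 0.28 ± 0.14 and just missed the threshold (adjusted p = 0.0576). The next genes above 0 on all 6 arrays did not pass either, with CNKSR2 at 0.21, MID1 at 0.18, RTN2 at 0.17, DNAJC12 and RSPO3 at 0.16, and ACBD6 and ARL6 at 0.14 (adjusted p from 0.153 to 0.266). Of the named genes that fell, WASHC2A and POLR1D, an RNA polymerase subunit gene at -0.31, each had a second, brighter probe with the opposite sign, at 0.09 and 0.14, neither past the threshold. Of 6733 probes, 758 had an unadjusted p under 0.05, where 337 would by chance, and the source of this excess was not tested. The count past the adjusted threshold, 30, was 67 without pair A, and 0 in limma with the goats compared unpaired, where 11 had an unadjusted p under 0.05. These 11 are fewer than chance would give, so the unpaired setting was conservative and its 0 does not show that no probe differs. For CSN1S1 the SD of the single-channel levels there was 0.65 over the Low goats and 0.77 over the High goats, against 0.13 between pair ratios. The 2 goats of a pair share their arrays, so these SDs cannot tell differences between arrays from differences between goats.

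**Figure D2:**
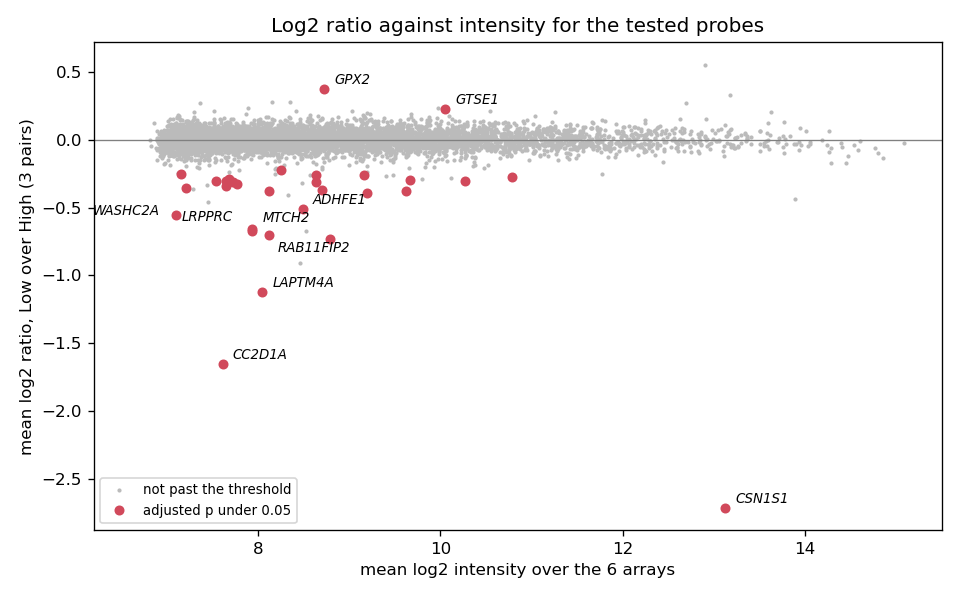
Mean log2 ratio of Low over High over the 3 pairs (vertical axis) against mean log2 intensity over the 6 arrays (horizontal axis), with 1 point per tested probe. Red points are the 30 probes with limma adjusted p under 0.05, 28 of them below 0. Of the other 29 red points, 16 lie below the median intensity of the tested probes.

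Gene lists fixed before the data were examined asked whether milk synthesis, secretion, stress and other cell types moved as groups. Only the ribosomal protein list passed among the 29 lists tested (limma camera, adjusted p = 0.00799), with a median log2 ratio of -0.043 over 44 genes, and its call was lost with an estimated correlation between genes (adjusted p = 0.988). Of the 44 genes, 29 were below 0 and 15 above. The list was fixed by name prefix, and 6 of its members are not ribosomal proteins: the kinases RPS6KB1, RPS6KB2, RPS6KA1, RPS6KA3 and RPS6KL1, and RPS19BP1. Without them, an alternative chosen after seeing the data, the median was -0.049 over 38 genes (adjusted p = 0.00124, and 0.988 with an estimated correlation), with 26 below 0 and 12 above. RPSA (-0.30), RPL22 (-0.29), RPL4 (-0.29) and RPLP2 (-0.26) fell, the same 4 when p was adjusted over the list alone, and the other 40 did not pass. RPSA and RPL4 each kept their call in 11 of 21 alternatives fixed in advance, and RPL22 in 16 of 20. RPSA and RPL4 were lower on the arrays with the Low goat in Cy3, at -0.64 to -0.53, and between -0.23 and 0.13 on those with the Low goat in Cy5. RPL22 was split likewise, at -0.59 to -0.42 with the Low goat in Cy3 and -0.15 to -0.016 with it in Cy5. For RPLP2 the values of the dye orientations overlapped. The list median was -0.018, -0.029 and -0.051 in pairs A, B and C. The list's call was also lost with median centring in place of the loess curve (median -0.020, adjusted p = 0.054) and in fry (adjusted p = 0.435), which asks whether the genes move 1 way on balance. The same held on a t-statistic without pooled variance (adjusted p = 0.257). Without the pair C array with the Low goat in Cy5 the median was -0.026 (adjusted p = 0.0242).

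The remaining lists that describe milk synthesis did not pass. Of the 11 measured milk protein genes, CSN1S1 fell and the other 10 did not pass over all probes. Adjusted over the list alone, CSN1S1, LTF and PAEP passed below 0 and LALBA above 0 (list median -0.020, adjusted p = 0.322). The glucose uptake and lactose synthesis list had 8 of 11 genes above 0, with SLC2A4, an insulin-dependent glucose transporter, at 0.21 and HK1, a hexokinase, at 0.11 (list median 0.041, adjusted p = 0.231). Adjusted over the list alone, only its member LALBA passed. The triacylglycerol and milk fat globule list had 8 of 12 genes above 0, with MGLL, a monoacylglycerol lipase, at 0.17 and MFGE8, a milk fat globule membrane protein, at 0.16 (list median 0.039, adjusted p = 0.322), and GPAM passed when adjusted over the list alone. Without pair C the lactose list (median 0.054, adjusted p = 3.51e-05) and the milk fat list (median 0.044, adjusted p = 0.0445) passed, but not with an estimated correlation (adjusted p = 0.994 for each). Without pair A the milk protein list passed (median -0.081, adjusted p = 0.00509), but not with an estimated correlation (0.964). With unpaired goats the lactose list (adjusted p = 0.0333) and the milk protein list (8.05e-04) passed, but not with an estimated correlation (0.481 and 0.339). The milk protein list holds CSN1S1 at -2.71, where its next largest change is LTF at -0.67. No test of that list without CSN1S1 is given, so its calls may rest on that gene alone. The estimated-correlation tests of these lists were run after the calls were seen. Their p rests on the pairs or goats left rather than on the number of genes. With so few a list can hardly pass, most of all without a pair, so these losses do not decide whether the calls hold.

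No gene of the other tested lipid lists passed. Fatty acid uptake and activation, with LPL, the lipoprotein lipase gene, at 0.10 and CD36 at -0.09, had a median of 0.027 over 10 genes. Fatty acid synthesis and NADPH supply, with TKT at -0.10 and ACO1 and PGD at 0.06, had a median of -0.0049 over 10 genes. Lipogenic regulators, with PPARGC1A, a transcriptional coactivator, at 0.14, had a median of -0.011 over 13 genes. Cholesterol synthesis, with TM7SF2 at -0.12, had a median of 0.0016 over 8 genes, and fatty acid oxidation and ketone metabolism, with ECHS1 at 0.12, a median of 0.017 over 11 genes. The 3 measured genes of fatty acid desaturation and elongation were too few to test as a list, and CYB5R3, a cytochrome b5 reductase gene, fell there by 0.25 ± 0.07 on the log2 scale (SD, n = 3; adjusted p = 0.0312), a call kept in 10 of 19 alternatives fixed in advance. The CYB5R3 probe was dim, above background in 3 of 6 Low and 4 of 6 High readings. Its spots lie near those of CSN1S1 without touching them.

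The genes of folding and secretion did not pass as groups. The endoplasmic reticulum stress and chaperone list had a median of 0.010 over 21 genes, of which 0 passed. Among its members CALR, the calreticulin gene, was at -0.10, ATF4, a stress transcription factor, at 0.10, and TRIB3 at 0.06. Protein translocation and vesicle transport, with SEC24C at 0.17, SRP19 at 0.14 and SEC13 at 0.10, had a median of -0.0083 over 31 genes. Translation factors, with PABPC1, the poly(A)-binding protein gene, at -0.32 (adjusted p = 0.205), had a median of -0.0042 over 30 genes. Amino acid transport had a median of -0.014 over 4 genes, with SLC3A2 at -0.06, and the proteasome list a median of 0.024 over 26 genes, with PSME1 at -0.19. Oxidative phosphorylation, with COX7A2L at 0.15 and ATP5MC2 at -0.11, had a median of -0.00032 over 44 genes.

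Stress, growth and cell death genes gave 1 call, GPX2, in the heat shock and oxidative stress list (median -0.0020 over 22 genes). Adjusted over the list alone, MT1A, a metallothionein gene at -0.26, and HSPA2, a heat shock protein gene at -0.13, passed as well. The programmed cell death and involution list had a median of -0.0014 over 23 genes, and only MCL1, an anti-apoptotic gene at 0.20, passed when adjusted over the list alone. Lactogenic hormone and growth factor signalling, with STAT3 at -0.25 ± 0.29 (SD, n = 3) and ERBB2 at -0.09, had a median of 0.0041 over 21 genes. The cell cycle list, with MCM3 at 0.14, had a median of -9.6e-05 over 26 genes.

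Markers of other cell types were measured to see whether tissue makeup differed between the genotypes, and none of their genes passed. Luminal epithelial markers, with KRT19 at -0.13 and its other probe at -0.04, had a median of -0.0085 over 15 genes. Myoepithelial and smooth muscle markers, with KRT17 at -0.10, had a median of -0.016 over 9 genes. Leukocyte markers, with ITGB2 at -0.16, FCGR2B at 0.15 and CD68 at 0.12, had a median of 0.0013 over 29 genes. Medians were -0.010 for fibroblast and matrix genes (SPARC at -0.13), 0.020 for adipocyte genes (LEP, the leptin gene, at -0.27), -0.0072 for endothelial genes (CDH5 at -0.08) and 0.0070 for skeletal muscle genes (CKM at -0.13). The LEP value had an SD of 0.34 (n = 3), and a second LEP probe of similar brightness gave -0.05. Medians were 0.0078 for plasma cell and immunoglobulin genes (IGHG1 at -0.11), -0.040 for MHC genes (BOLA-DRB3 at -0.11) and 0.019 for interferon response genes (IFI44L at -0.11). Only 1 red blood cell marker, ALAS2, was measured, at -0.003. Adjusted p for the 28 lists that did not pass were at least 0.231. For 9 of them the median, the mean and the test did not share a sign, and no direction is read from these.

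**Figure D3:**
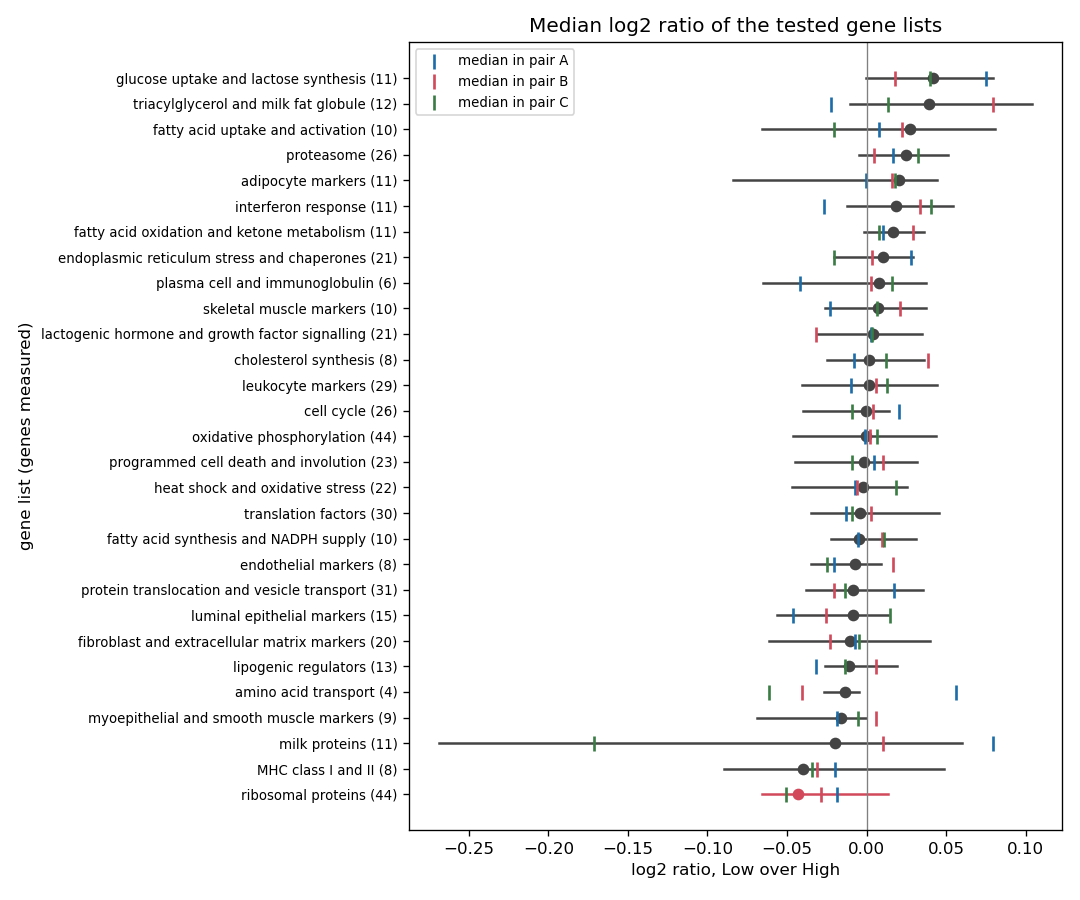
Median log2 ratio of Low over High (horizontal axis) for the 29 tested lists (vertical axis, number of genes measured in brackets). Dots are medians over genes of the mean of the 3 pairs, bars run from the lower to the upper quartile of the genes, and ticks are the medians in each pair. Only the ribosomal protein list (red, median -0.043) passed the threshold.

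Agreement between arrays showed how far the difference was shared. The pair means of CSN1S1 and all other tested probes correlated across probes at r = 0.34 (A with B), 0.35 (A with C) and 0.42 (B with C). These are correlations across probes, which are not independent replicates. Across probes the pair means had an SD of 0.093, 0.10 and 0.12 in pairs A, B and C. CSN1S1, at -2.57, -2.84 and -2.73, therefore weighs heavily in r. No correlation without it is given, so how much the other probes share is not shown. Once both were turned to Low over High, the 2 arrays of a pair correlated at -0.54, -0.54 and -0.13 in pairs A, B and C, a mean of -0.40, so differences tied to the dye outweighed the genotype difference on a single array. With print-tip loess, which fits each printed block, this mean was -0.14, and with block medians and no background correction -0.17. The dye effect was shared between pairs (r = 0.84, 0.72 and 0.71 across probes), and averaging the 2 arrays removed most of it. Regressed on the dye effect of the other pairs, the pair means had slopes of -0.0068 (A), -0.032 (B) and -0.18 (C), so part of it remained in pair C. Across probes the dye effect had an SD of 0.17, 0.19 and 0.13 in pairs A, B and C. LPL had the largest among the named genes, a dye effect of 0.78 beside a mean log2 ratio of 0.10.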

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

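Chosen or reworded only after the result was seen were the tests of spill-over and of CSN1S1 material on other probes, the test of LRPPRC, the median centring test of LALBA, CSN1S2 and PAEP, and the tests on 38 ribosomal proteins, while the other tests here were written before.

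The first pattern is that 27 other probes fell together with CSN1S1, several of them dim. Spill-over from the bright CSN1S1 spots would place them beside these spots, but 26 lay farther than 2 spot lines or 4 spot columns away, all but CYB5R3, and the 8 probes touching the CSN1S1 spots had log2 ratios from -0.11 to 0.09. For CYB5R3, inside that window but not touching the spots, spill-over is not excluded. CSN1S1 material on other probes would give each a steady share of the CSN1S1 signal difference, and 3.70% of the 27 (1 probe) kept one, but the arrays of a pair differ too much for the share to decide, so carried or cross-hybridizing material cannot be told apart from a real fall. For LRPPRC, numbered next to CSN1S1, the larger share in the other pairs was 0.236 of that in A, but the share alone cannot decide here either. Its High minus Low difference itself was at least 147 on the arrays of A and at most 117 on the others, where that of CSN1S1 was larger. This speaks against carried oligo as the only source there. It rests on the 2 arrays of 1 pair, in a test worded after the result was seen, and does not exclude a part from carried oligo. LRPPRC is 1 of 4 among the 27 probes with a larger difference on both arrays of A. First versions of these tests took the 1 probe beside the spots as enough for spill-over, and a later version that set 12 probes apart was dropped, because the smaller CSN1S1 difference in A raises every share there.

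The second pattern is the fall of the ribosomal protein list. After regression on the dye effect 97.9% of its median fall was left, and with a loess curve per printed block 89.9%. Of 10000 random lists matched on intensity, 0.01% had a median as low, and 0.02% with median centring. For the 38 members that are ribosomal proteins the same 3 tests, chosen after the result was seen, gave 95.9%, 87.6% and 0.01%. The block and intensity tests argue against position and intensity as the whole cause. The regression decides little about dye, because the list's median dye effect was only -0.0049 and little could be removed. The median of the 44 genes was below 0 in both dye orientations, at -0.053 with the Low goat in Cy5 and -0.041 with it in Cy3. For RPSA, RPL4 and RPL22, which were split by dye, a remaining dye effect is not excluded. A small genotype difference may remain as a hypothesis. The call was lost with an estimated correlation between genes (adjusted p = 0.988). That test rests on the 3 pairs rather than on the number of genes, and 0 of the 29 lists passed it. It therefore cannot decide whether these genes co-vary, and co-variation among them in 3 pairs stays open.

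The third pattern is that LALBA, CSN1S2 and PAEP differed between the pairs. With median centring in place of the loess curve each kept at least 100.3% of its range over the pairs, and 0 of their spots were saturated. The median centring test replaced a first one, leaving CSN1S1 spots out of the loess curve, which moved nothing. A test of the spread between spots against that between arrays was run and dropped, since it sets single samples against technical noise. Differences between goats, such as stage or response to food deprivation, may account for the pattern but were not tested, as the 100.3% left speaks only against the loess curve.

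Assignments of Low and High within the 3 pairs number 4, too few for a share under 0.05: the real one gave 30 probes and the highest other 0, and the real one gave 1 list and the highest other 0, so that 1 of the 4 gave as many in each case.

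In 60 groups of 6 arrays, 4 had 1 array far from the others, where chance gives about 1 in 20. FYN was at -0.60 on the pair A array with the Low goat in Cy3, against -0.40 to -0.29 on the others. RTN2 was at 0.36 on the pair C array with the Low goat in Cy3, against 0.09 to 0.18. ACBD6 was at 0.41 on the pair B array with the Low goat in Cy3, against 0.0062 to 0.14. The interferon response list had a median of 0.11 on the pair C array with the Low goat in Cy5, against -0.035 to 0.0065.

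Spots without a probe, which the comparisons do not use, were read as well. Of 10872 readings at blank spots 1.47% stood above background, and of 18432 readings at empty spots 0.152% did, above the 0.0276% and 0.0163% that a count of 0 allows, and 0 readings lay as far below background. None was above in all 12 readings (0 spots), and whether the readings hold labelled RNA was not tested.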

How the results depend on the processing

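The 4 alternatives chosen after seeing the data were the loess curve without CSN1S1 spots and the dye effect regressed out (30 probes each), 5 arrays without the pair C array with the Low goat in Cy5, and the ribosomal list without 6 members that are not ribosomal proteins (median -0.049, adjusted p = 0.00124, and 0.988 with estimated correlation). The count of 30 became 19 with offset 10, 59 with 6 arrays and pair as a random block (correlation of paired arrays -0.0785), 1153 with only Low in Cy5 and 2453 with only Low in Cy3, where dye effects do not cancel by construction. The random-block fit without the pair C array gave 30 probes in place of 59, of which 23 are among the 30 from the pair means, and a ribosomal median of -0.026 (adjusted p = 0.0242). It became 0 in the t-test (503 at unadjusted p under 0.05) and 0 with unpaired goats in limma (11 at unadjusted p under 0.05). Leaving out a pair gave 24 to 67 probes and 1 to 3 lists, and the other settings 21 to 44 probes. Of the 30 probes, 27 were still called without pair A, 16 without pair B and 26 without pair C. The count of lists, 1, became 0 with median centring, the t-test, only Low in Cy5, only Low in Cy3, estimated correlation and fry, and 3 with unpaired goats. The ribosomal list median was -0.020 with median centring (adjusted p = 0.054), -0.043 in the t-test (0.257), -0.053 with only Low in Cy5 (0.658), -0.041 with only Low in Cy3 (0.843), -0.043 with estimated correlation (0.988) and -0.043 in fry (0.435), and -0.034 to -0.026 leaving out a pair. It passed in 22 of 28 alternatives. CSN1S1 stayed negative throughout, at -2.71 without passing in the t-test (adjusted p = 0.657) and with unpaired goats, and at -2.78 to -2.65 leaving out a pair. With only Low in Cy3, LPL (-0.68), CLU (0.29), BOLA-DMB (-0.15) and ALAS2 (0.14) passed with the opposite sign, and with only Low in Cy5 BOLA (0.30) did. Agreement of dye-swapped arrays was -0.14 with print-tip loess and -0.17 with block medians and no background correction, against -0.40, and that of pairs 0.326 without the filter. Values that stayed past no threshold but changed sign were counted as unchanged: 109 of 810 list medians and 48 of 2709 named-gene values. Apart from single dye orientations the cause was not tested. Signal over background (2.67 to 6.00) limits dim probes.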

Other observations

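All observations here were chosen only after the values were seen. SPP1, the gene of the milk protein osteopontin, had the lowest mean log2 ratio of the probes that did not pass, -0.91 ± 0.87 (SD, n = 3; limma adjusted p = 0.236), with -1.67, -1.08 and 0.03 in pairs A, B and C. LTF gave -1.31, -0.35 and -0.35 in the same pairs.

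RAB11FIP2 and a probe without a symbol, Bt00005040, differed by at most 0.15 on every array, the closest of 6732 probes, and the next differed by up to 0.36. RPSA and RPL4 differed by at most 0.10 on every array, where the next closest probe to RPSA differed by up to 0.14. No probe sequences were used here, so whether the probes of a pair share a target was not tested.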
